A study of Danio rerio with 32 samples.

How the data were processed

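RNA from whole zebrafish embryos was extracted with Qiazol, and polyadenylated RNA was made into strand-specific libraries with the NEBNext Ultra II Directional kit, per the labels' protocols. The series holds 32 libraries in 4 groups of 8: control, all-trans retinoic acid, valproic acid and folic acid. Groups were taken from the treatment given in the labels and replicate numbers were given in accession order within each group. Titles carry numbers up to 48, and each set of 12 consecutive numbers holds 2 libraries of every group. Nothing in the labels says whether the libraries of a group came from separate clutches, days or pools, or what the title numbers stand for.

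The deposited table gives normalized expression on a log2 scale for 15710 Ensembl genes, 1 column per library. HTSeq 0.11.0, limma and the genome build GRCz11 are named per the submitters' processing notes. The aligner, the annotation release, the filter on low genes and the normalization step are not given in the sources used here. The values ran from 0 to 19.4, and the 1000 highest ranked values of any library differed from those of any other by at most 0.03, which is what quantile normalization gives. Quantile normalization sets the distribution of every library equal, so a change in the total amount of RNA, or of most genes in 1 direction, would not be seen. Library totals cannot be had from such values. Relative depth was estimated from the steps between low values, as the number of reads at the lower-quartile gene, and ranged from 12 to 52. It was lowest in folic acid replicates 7 and 8, at 12 and 13.

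The design assumed a count table or normalized values, with a test for each. Because the table holds normalized log2 values, the branch for these was used, without a pseudocount. The main test was limma 3.58.1 in R 4.3.3, with a mean per group, all 32 libraries in 1 fit, empirical Bayes with an intensity trend and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. A filter at a mean log2 value of 1 was set, and it removed 0 genes, since the lowest mean was 2.13. SE and 95% confidence intervals come from the same fit, and the median half-width of the interval was 0.362. The tests, the lists, the rule for named genes and 6 other settings were fixed before the data were examined. The 2-fold counts use an absolute log2 fold change of at least 1.

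The 25 gene lists were tested with camera in limma with its preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated per list. Of 935 list genes, 754 matched a name in the identifier table, 285 exactly, 292 ignoring case and 177 after removing the letter that marks a paralog, and 181 were not matched. A name without that letter can stand for either paralog. Reads shared between near-identical copies may be left out or misassigned in the counting, so values of paralogs are uncertain to that extent. Names were found for 15016 of the 15710 identifiers, and 1503 identifiers share a name with another, so the identifier is given for such genes. No genome was used, so no coordinates are given.

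Genes were named by a rule. For each comparison with control it takes the 10 largest rises and the 10 largest falls among called genes in the upper 75% by mean, with a name other than a clone name and the same sign in each of the 4 sets of title numbers. It adds up to 4 called members of each list with the smallest adjusted p, and always CYP26A1, DHRS3, ALDH1A2, hoxb1b, hoxb1a, HDAC1, tbxta, SOX3 and OTX2. Some genes that the rule names are not reported here.

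The fit was tested on simulated data made from residuals shuffled over all libraries on the control means, with 200 of 15710 genes changed. Each comparison rested on 5 simulated sets made in the same way, so differences in recovery between comparisons are those of the draws. This shuffling also broke up the title-number sets. Valproic acid itself changed 31.3% of genes, so the shares below do not carry over to it. Changes of 1.41-fold, 2-fold and 4-fold were recovered in 32.2%, 58.2% and 93% of cases for retinoic acid against control and in 32.5%, 69.9% and 93.3% for valproic acid against control, and 2.24% and 0.611% of the calls were false. Camera with its preset correlation called 8.6% to 23.2% of simulated lists that had not been moved, and 0 with an estimated correlation, so preset calls alone are liberal. The folate and one-carbon list, with all 41 genes moved by 0.5, was called in 20 of 20 simulations in both ways. Its estimated correlation was 0.052, against 0.71 for the Hox and Cdx list. This simulation therefore does not show what can be recovered in lists of higher correlation. The correlation was estimated without the title-number sets in the fit, so differences between sets enter it.

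The other settings fixed in advance were limma without the trend, median centring, no filter, the title-number sets as a block, the mean of the 2 libraries of each group and set, and only the compared groups in the fit. Added after the data were seen were array weights, a mean above 5, leaving out the 2 libraries of lowest weight, leaving out the libraries numbered 25 to 36, a depth covariate, removal of each library's trend on level, and leaving out each library in turn. Tests for counts and another pseudocount were not applicable to these values. Calls shared by retinoic acid and valproic acid were set beside the overlap of independent lists, 100 simulations of unchanged groups against the same controls, and the overlap with the controls split by odd and even replicate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.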

Results

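Gene expression was measured by sequencing of polyadenylated RNA from whole zebrafish embryos in 4 groups of 8 libraries. Embryos were exposed for 4 h, from 3 to 7 h after fertilization, a window that covers the start of gastrulation. The compounds were all-trans retinoic acid, a vitamin A metabolite that acts as a ligand of nuclear receptors, valproic acid, an antiepileptic drug that inhibits histone deacetylases, and folic acid, a vitamin that the series design names as the negative control. Control embryos were kept in the rearing water with 0.01% DMSO. The labels give no doses, so the size of the responses cannot be compared at matched doses. The table holds 15710 genes on a log2 scale that is the same in every library, so a difference of 1 is a 2-fold difference. Values below are means ± SD over 8 libraries per group, and differences are given as log2 fold changes with their SE. The labels do not say what separates the replicates of a group, so p-values measure the spread between these libraries, which may be technical.

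The valproic acid libraries stood apart from all others along the first principal component, which carried 19.1% of the variance. They lay between -70.5 and -31.4 on it, and the lowest library of any other group lay at -11.5. The second component, with 13.3% of the variance, separated libraries by the number in their titles. The 6 libraries numbered 25 to 36 in the control, retinoic acid and folic acid groups lay between -51.8 and -29.8. The other libraries of these groups lay at -13.8 or above, except control replicate 1 at -37.7. Each set of 12 title numbers holds 2 libraries of every group, so this split is balanced over the groups. The libraries numbered 37 to 48 also stood apart, along the fourth component, with 7.42% of the variance. In all 4 groups they lay between -43.0 and -21.9 on it, and every other library lay at -5.98 or above. Relative depth, estimated as the number of reads at the lower-quartile gene, ran from 12 to 52 reads. It did not differ detectably from the control group in retinoic acid (two-sided exact permutation test, p = 0.685), valproic acid (p = 0.799) or folic acid (p = 0.384). The ratio of estimated reads at the 40th to the 25th percentile, which describes the low part of the distribution before normalization, was 2.40 ± 0.0504 in valproic acid and 2.54 ± 0.0875 in controls. This was a difference of -0.136 (two-sided exact permutation test, p = 0.00171, adjusted p = 0.00513 over 3 comparisons), and the ratio did not differ detectably in retinoic acid (p = 0.253) or folic acid (p = 0.457).

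**Figure D1:**
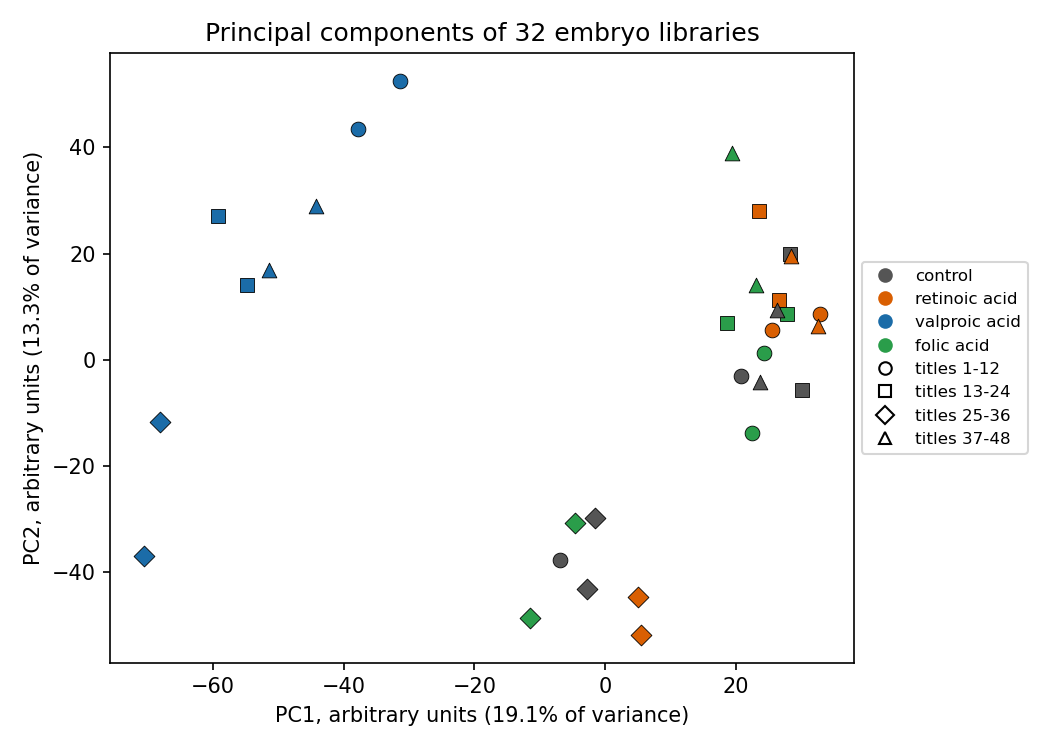
Each point is 1 of the 32 libraries, placed by its first and second principal component in arbitrary units, with the share of variance on each axis; color gives the group and shape the set of 12 title numbers. The 8 valproic acid libraries lie at -31.4 or below on the first component, and the libraries numbered 25 to 36 lie lowest on the second within each group, together with control replicate 1.

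The comparison of retinoic acid with control asks which genes respond to a teratogen whose receptors are present in the embryo. Among genes that handle retinoic acid itself, CYP26A1, the enzyme that degrades retinoic acid, rose 2.87-fold, from 12.91 ± 0.11 in controls to 14.43 ± 0.048 (log2 fold change 1.52, SE 0.08, limma adjusted p = 3.3e-15). DHRS3, a retinal reductase that lowers the supply of the precursor, rose by 1.06 (SE 0.10, adjusted p = 8.4e-09) under the identifier ENSDARG00000044803, and the receptor gene raraa rose by 0.94 (SE 0.15, adjusted p = 0.00018). ALDH1A2, the enzyme that makes retinoic acid from retinal, fell by 0.37 (SE 0.08, adjusted p = 0.0079). A second gene named DHRS3, ENSDARG00000044982, was at 8.18 ± 0.735 in retinoic acid and 4.44 ± 2.35 in controls, with 1 control library at its lowest value (adjusted p = 0.051). It passed in 9 of the 32 fits without 1 library, without control replicate 2, 3 or 4, valproic acid replicate 1, 2, 3 or 6 or folic acid replicate 5 or 6, with adjusted p from 0.028 to 0.17 over all 32. Of the 26 measured genes of retinoic acid metabolism and reception, 3 rose, 1 fell and 22 did not pass, and 8 rose and 1 fell when adjusted over the list alone. The list was higher as a set by camera (adjusted p = 1.6e-09), and this was the 1 list of the comparison whose call held with an estimated correlation (adjusted p = 0.00086).

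Homeobox genes of the Hox clusters pattern the hindbrain and trunk. Of 25 measured Hox and Cdx genes, 9 rose and none fell, and 12 rose when adjusted over the list alone. HOXA3 was near the lowest measurable values in controls, at 2.18 ± 1.43, and at 8.04 ± 0.40 in retinoic acid (adjusted p = 1.2e-07). HOXD4 went from 1.90 ± 1.55 to 5.84 ± 0.754 (adjusted p = 0.00038), and hoxc1a from 3.24 ± 1.08 to 6.87 ± 0.536 (adjusted p = 3.2e-05). HOXB5 (ENSDARG00000054030) rose by 4.11 (SE 0.60, adjusted p = 5.9e-05), HOXB3 by 1.84 (SE 0.35, adjusted p = 0.0024) and hoxb1a by 2.69 (SE 0.53, adjusted p = 0.0038). The early hindbrain gene hoxb1b rose by 1.55 (SE 0.38, adjusted p = 0.035). The Hox and Cdx list was higher as a set (camera adjusted p = 4.4e-30), with adjusted p = 0.058 with an estimated correlation, which was 0.71 among its members. That value was between 0.033 and 0.05 in 8 of the 32 fits without 1 library, without control replicate 2, 3 or 4, valproic acid replicate 1, 2 or 6 or folic acid replicate 5 or 6. The same list was also lower in the libraries numbered 25 to 36, by a median of -1.61 over the 3 groups other than valproic acid.

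**Figure D2:**
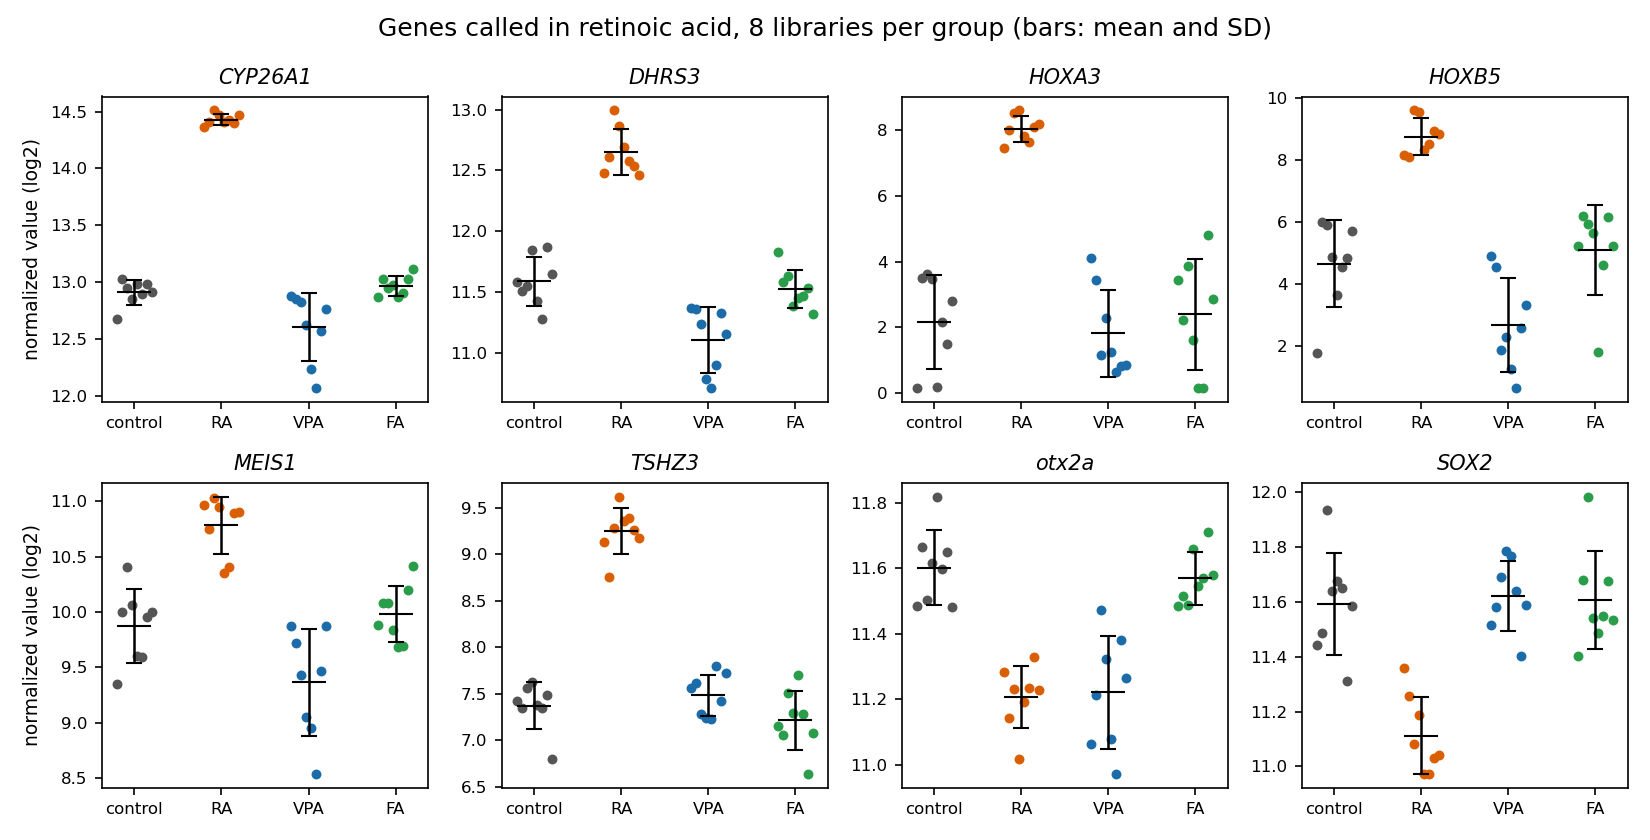
Normalized log2 values of 8 genes called in retinoic acid, with 1 point per library, 8 per group, and bars for the mean and SD; RA is retinoic acid, VPA valproic acid and FA folic acid. CYP26A1 lies near 14.43 in retinoic acid and near 12.91 in controls, and otx2a lies near 11.21 in retinoic acid, near 11.22 in valproic acid and near 11.6 in controls.

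Of 20 measured hindbrain and spinal cord patterning genes, 3 rose and none fell (5 rose when adjusted over the list alone), among them the Hox cofactor MEIS1, by 0.91 (SE 0.16, adjusted p = 0.00088). Of 26 measured genes of the anterior neural plate and midbrain, 2 fell and none rose, and 4 fell and 1 rose when adjusted over the list alone. The 2 calls over all genes were otx2a, by -0.39 (SE 0.07, adjusted p = 0.00043), and OTX1, by -0.43 (SE 0.09, adjusted p = 0.0059), both forebrain and midbrain transcription factors. Among 45 measured neural progenitor and neurogenesis genes, 7 rose and 1 fell, and 10 rose and 3 fell when adjusted over the list alone. INSM1, a zinc finger gene of differentiating neurons, rose by 1.62 (SE 0.23, adjusted p = 3.9e-05), ELAVL3, an RNA-binding protein of neurons, by 2.02 (SE 0.38, adjusted p = 0.0018), and SOX3 by 0.33 (SE 0.06, adjusted p = 0.00086), while the progenitor gene SOX2 fell by 0.48 (SE 0.08, adjusted p = 0.00048). The hindbrain list (camera adjusted p = 8.2e-05) and the neurogenesis list (adjusted p = 0.00032) were higher as sets and the anterior list was lower (adjusted p = 0.00024). With an estimated correlation none of these held, with adjusted p = 0.18, adjusted p = 0.14 and adjusted p = 0.42 in that order. The libraries numbered 25 to 36 were also lower in the anterior list, by a median of -0.46, in the hindbrain list, by -0.24, and in the neural border list, by -0.30 with 12 of 24 genes lower. The neural border list (24 measured) and the BMP list (31 measured) were higher as sets (adjusted p = 0.00051 and 8.7e-05) with no member rising over all genes tested. In the BMP list chrd fell over all genes tested. Adjusted over the list alone, 4 and 8 members rose and 1 fell in each list. With an estimated correlation they gave adjusted p = 0.32 and adjusted p = 0.13.

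Signaling genes among the smaller changes included DUSP6, a feedback phosphatase of the FGF pathway, which rose by 0.65 (SE 0.06, adjusted p = 1.7e-09), and FGF8, which rose by 0.48 (SE 0.08, adjusted p = 0.00078). The Wnt target sp5l rose by 0.39 (SE 0.06, adjusted p = 8.1e-05) and the Wnt receptor gene FZD8 (ENSDARG00000045444) fell by 0.37 (SE 0.06, adjusted p = 0.00018). The FGF and MAPK list had 3 of 31 measured members higher, and the Wnt list 1 higher and 2 lower of 32, and neither was called as a set (camera adjusted p = 0.19 and 0.062). TBXT (ENSDARG00000039806), a brachyury gene of mesoderm and notochord, fell by 0.94 (SE 0.20, adjusted p = 0.0096), while tbxta, the other brachyury gene, differed by -0.13 (SE 0.11, adjusted p = 0.97). OTX2 differed by -0.08 (SE 0.17, adjusted p = 0.98) and HDAC1 by 0.03 (SE 0.05, adjusted p = 0.97). No member of the lists for histone deacetylases, HDAC inhibitor targets, fatty acid oxidation, oxidative stress, heat shock and unfolded protein, p53 response, cell cycle, maternal transcripts, enveloping layer, yolk syncytial layer or germ cells passed the test, also when adjusted over the list alone. Of 35 early zygotic and pluripotency genes 3 rose and 1 fell, of 47 Nodal and mesendoderm genes 2 fell and of 30 organizer, notochord and prechordal plate markers 2 rose and 3 fell, and camera called none of these lists (adjusted p = 0.78, 0.055 and 0.19). The Nodal list passed without control replicate 1, 4, 7 or 8, retinoic acid replicate 3 or 6 or valproic acid replicate 7 (adjusted p from 0.0034 to 0.046) and, narrowly, with the title-number sets as a block (0.05 after rounding), the organizer list without retinoic acid replicate 3 (0.042), and the Wnt list without control replicate 1 or retinoic acid replicate 1, 4 or 6 (0.013 to 0.046). None of these 3 lists passed with an estimated correlation in any fit without 1 library, and with all libraries they then gave adjusted p = 0.59 for Nodal, adjusted p = 0.61 for the organizer and adjusted p = 0.49 for Wnt. AHCYL1 was the 1 gene called among 41 of folate and one-carbon metabolism, at 1.16 (SE 0.24, adjusted p = 0.0065), and tiparp the 1 gene called among 22 of xenobiotic metabolism, at 0.62 (SE 0.07, adjusted p = 3.1e-07).

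In all, 93 genes rose and 22 fell with retinoic acid, and 47 of the rises and 3 of the falls were at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). The largest rises under the naming rule included oc90, a component of the otic extracellular matrix, by 2.98 (SE 0.38, adjusted p = 5.9e-06), skap1 by 2.95 (SE 0.49, adjusted p = 0.00034), HES6 (ENSDARG00000007097) by 2.39 (SE 0.32, adjusted p = 1.4e-05), hephl1a by 2.23, ugt5g1 by 1.89 and the zinc finger gene TSHZ3 by 1.87 (SE 0.14, adjusted p = 1.3e-11). The falls were smaller, with rasd2a at -1.33 (SE 0.28, adjusted p = 0.0069), NPR3 at -0.79, RASL11B at -0.57, the forebrain gene lhx5 at -0.57 and AMOTL2 at -0.52. The falls of sall3b (-0.80), arhgef37 (-0.60), dnase1l1 (-0.54), chrd (-0.37) and admp (-0.40) and the rise of hoxb1b were each lost in 7 to 21 of the 32 fits that left out 1 library, for all 6 genes without control replicate 1 or 2 or retinoic acid replicate 4, with adjusted p up to 0.16, 0.084, 0.12, 0.12, 0.12 and 0.11 in that order. In each set of 12 title numbers taken alone, 2 libraries against 2, limma called 67, 2, 32 and 13 genes, and 114 of the 115 genes had the same sign in all 4 sets. When the 2 libraries of each group and set were averaged, which leaves 4 values per group, 36 genes were called, 22 of them at least 2-fold and all 22 higher. With the sets as a block, 199 genes were called, and 74 rises and 10 falls were at least 2-fold. Among genes with a mean above 5, 30 rises and 1 fall were.

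**Figure D3:**
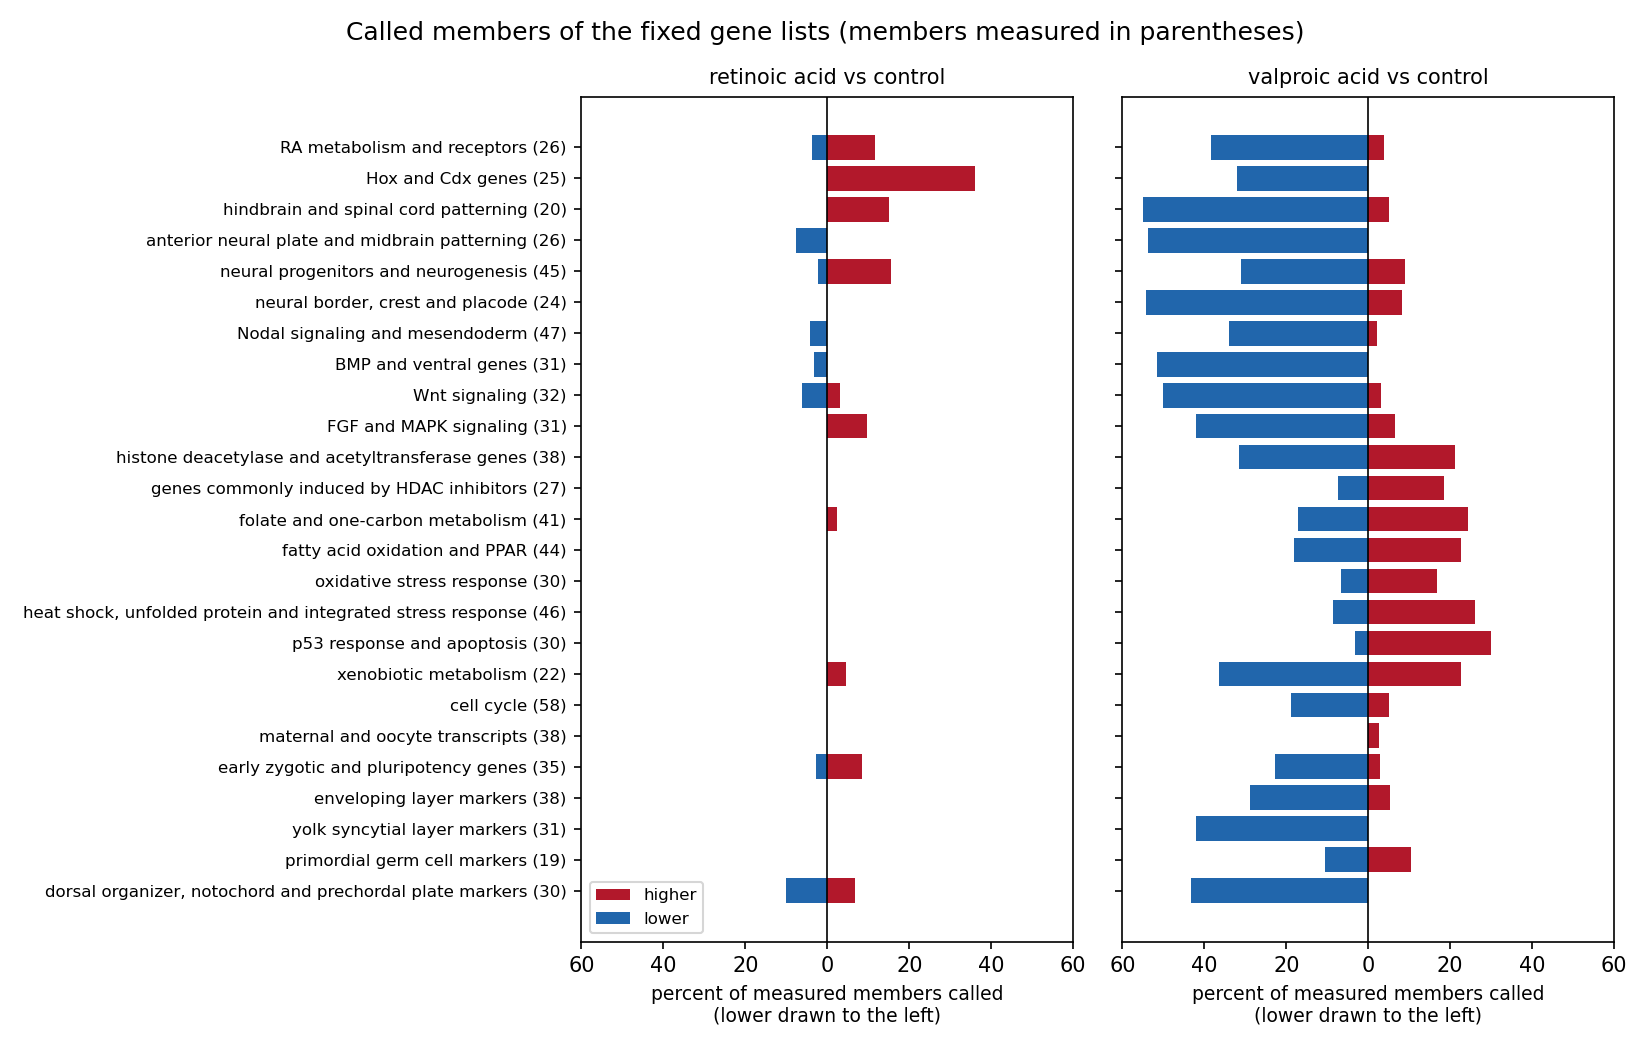
For each of the 25 gene lists, bars give the percent of measured members called higher, to the right, and lower, to the left, by limma in retinoic acid and in valproic acid against control, with the members measured in parentheses. Hox and Cdx genes were called higher in 9 of 25 members in retinoic acid and lower in 8 of 25 in valproic acid.

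Valproic acid, set against control, tests the response to an inhibitor of histone deacetylases. Of 15710 genes, 2505 rose and 2414 fell against control, 31.3% of those tested, and 646 rises and 555 falls were at least 2-fold. Among genes with a mean above 5, 291 rises and 352 falls were at least 2-fold, so the excess of rises did not hold there. The largest rises under the naming rule included the kinase gene FYN, by 2.42 (SE 0.31, adjusted p = 4.2e-07), CHKA, choline kinase, by 2.29 (SE 0.19, adjusted p = 1.1e-10), which is a 4.89-fold rise, and the actin crosslinkers FLNC (ENSDARG00000018566), by 2.32 (SE 0.24, adjusted p = 4.9e-09), and ACTN1, by 2.14 (SE 0.28, adjusted p = 4.5e-07). They also included vamp5 at 2.38 (SE 0.23), the synaptophysin gene sypb at 2.17 (SE 0.27) and ATP6V1B2 (ENSDARG00000043465), a subunit of the vesicular proton pump, at 2.07 (SE 0.19). ITPR1 (ENSDARG00000014655), the calcium release channel of the endoplasmic reticulum, rose by 2.32, ANKH (ENSDARG00000014969) by 2.18, with 1 control library at its lowest value, and FJX1 by 2.05. The largest falls under the naming rule included HAPLN1 at -2.70 (SE 0.47, adjusted p = 4.1e-05), a linker of hyaluronan matrix, ccndx at -2.41 (SE 0.56, adjusted p = 0.0012), both with 1 valproic acid library at its lowest value, GADD45G (ENSDARG00000016725) at -2.31 (SE 0.27, adjusted p = 6.3e-08), exoc3l1 at -2.30, btr01 at -2.15, kng1 at -2.09, noxo1a at -2.05 (SE 0.12, adjusted p = 2.5e-14), HMGXB4 at -1.92, ugt1b7 at -1.87 and PHOX2A at -1.83.

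**Figure D4:**
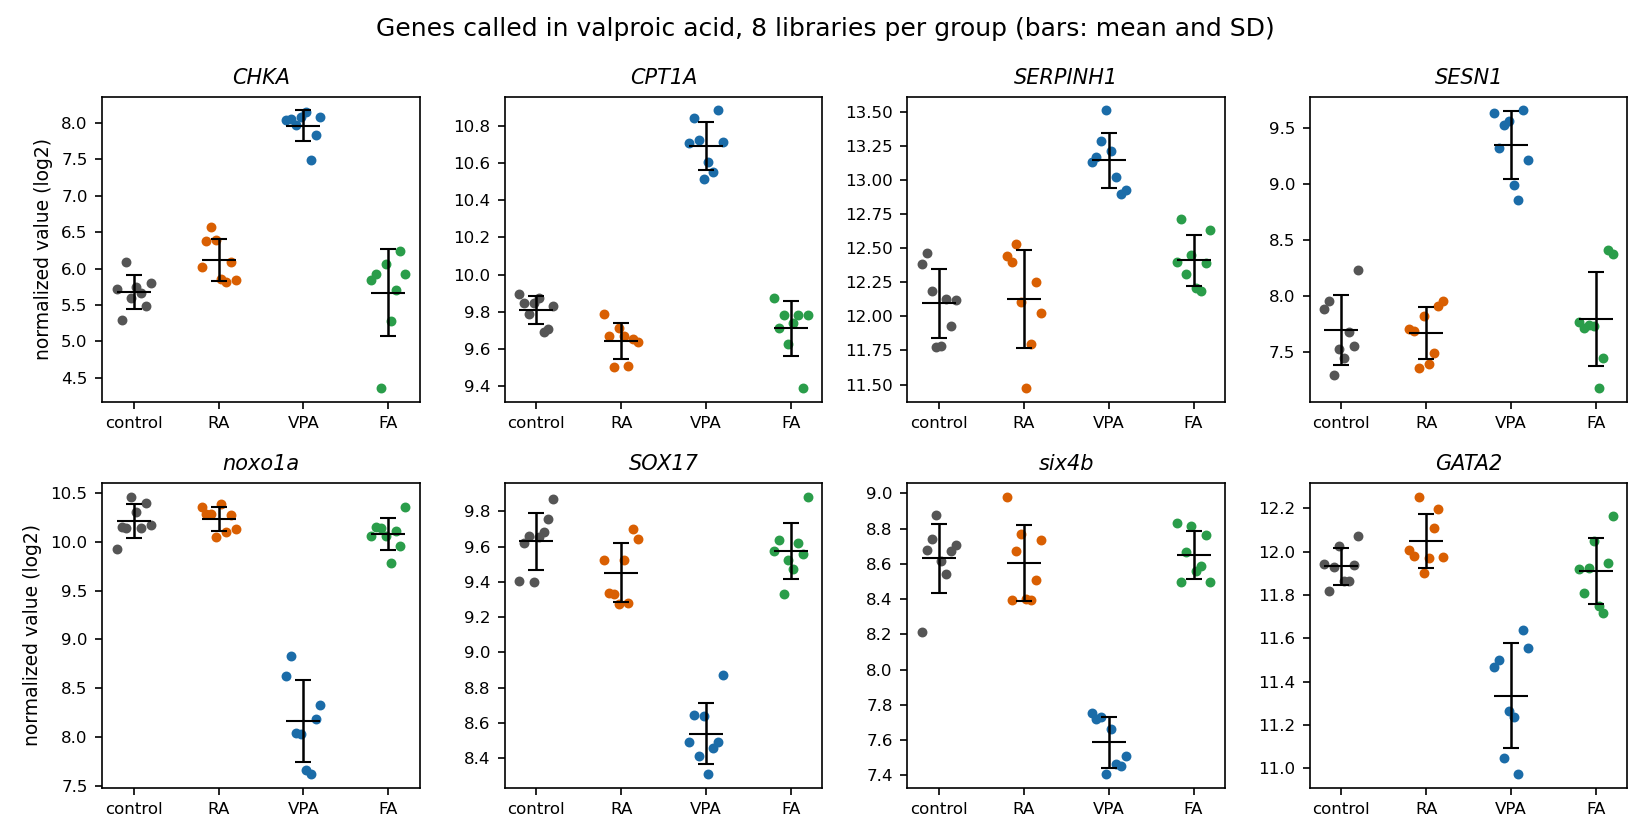
Normalized log2 values of 8 genes called in valproic acid, with 1 point per library, 8 per group, and bars for the mean and SD; RA is retinoic acid, VPA valproic acid and FA folic acid. CHKA lies near 7.96 in valproic acid and 5.67 in controls, and SOX17 near 8.54 and 9.63.

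Of 26 measured anterior neural and midbrain genes, 14 fell in valproic acid and none rose, including the secreted Wnt antagonist SFRP5, by -2.47 (SE 0.38, adjusted p = 6.8e-06) with 1 valproic acid library at its lowest value, otx2a, by -0.38 (SE 0.07, adjusted p = 3.9e-05), and OTX1, by -0.40 (SE 0.09, adjusted p = 0.00063). OTX2 differed by -0.36 (SE 0.17, adjusted p = 0.093) and passed without control replicate 1 or valproic acid replicate 1 (adjusted p down to 0.043). Of 45 neural progenitor and neurogenesis genes, 14 fell and 4 rose, with the motor neuron gene ISL1 at -2.51 (SE 0.42, adjusted p = 2.7e-05), where 3 of the 8 valproic acid libraries were at their lowest value and the size of the fall is not exact, the Notch ligand gene dlc at -0.50 (SE 0.09, adjusted p = 5e-05) and sox19b at -0.47 (SE 0.08, adjusted p = 6.8e-05), while SOX3 differed by 0.07 (SE 0.06, adjusted p = 0.37). Of 24 neural border, crest and placode genes, 13 fell and 2 rose, with six4b at -1.04 (SE 0.10, adjusted p = 1.5e-09) and foxi1 at -0.56 (SE 0.09, adjusted p = 3.1e-05). Of 20 hindbrain and spinal cord genes, 11 fell and 1 rose. As sets these 4 lists were lower (camera adjusted p = 4.8e-05 anterior, 0.043 neurogenesis, 0.004 border and 0.0021 hindbrain). Adjusted over the list alone, 14, 15, 13 and 13 members fell and 0, 4, 2 and 1 rose. Within the valproic acid group these lists were also lower in the libraries numbered 25 to 36, by medians of -0.64, -0.21, -0.48 and -0.37 in that order. None of the 4 held with an estimated correlation, where they gave adjusted p = 0.22, adjusted p = 0.34, adjusted p = 0.33 and adjusted p = 0.28. The neurogenesis call also ended without control replicate 3 (adjusted p = 0.074) or 4 (0.06) or valproic acid replicate 5 (0.06), 6 (0.085) or 7 (0.057), and with the mean of the 2 libraries of each group and set (0.055).

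Of 25 Hox and Cdx genes, 8 fell in valproic acid and none rose, and 8 fell when adjusted over the list alone. HOXC8 was at 4.78 ± 2.00 in valproic acid and 7.35 ± 1.18 in controls (adjusted p = 0.00092), and hoxc3a at 4.51 ± 2.80 and 7.60 ± 1.36 (adjusted p = 0.003). Both differed in the other direction in the set numbered 1 to 12, by 0.41 and 1.13, and fell in the other 3 sets, and hoxc3a was at the lowest value of 2 valproic acid libraries. The other 2 members that the naming rule takes also went the other way in that set. The 2 controls of that set include control replicate 1, which deviated in the direction of libraries 25 to 36, where this list was lower. Whether this bears on the reversals was not tested. The gene hoxb1b fell by 1.08 (SE 0.38, adjusted p = 0.026), a call that ended without control replicate 3 or 4 or valproic acid replicate 5 or 6 (adjusted p up to 0.078) and that went the other way in the set numbered 1 to 12 (0.66). The gene hoxb1a differed by -1.24 (SE 0.53, adjusted p = 0.072) and passed without valproic acid replicate 1 or 2 or folic acid replicate 6 (down to 0.028). It also went the other way in that set (0.19), and 1 valproic acid library was at its lowest value. The list was lower as a set (camera adjusted p = 0.00027), with adjusted p = 0.51 with an estimated correlation. Within the valproic acid group, too, the list was lower in the libraries numbered 25 to 36, by a median of -1.61. Of 26 genes of retinoic acid metabolism and reception, 10 fell and 1 rose, including rxrbb at -0.98 (SE 0.12, adjusted p = 2e-07), DHRS3 (ENSDARG00000044803) at -0.48 (SE 0.10, adjusted p = 0.00038) and CYP26A1 at -0.31 (SE 0.08, adjusted p = 0.0046), which differed by 0.02 in the set numbered 1 to 12. ALDH1A2 differed by 0.09 (SE 0.08, adjusted p = 0.44). Adjusted over the list alone, 11 fell and 2 rose. This list gave a camera adjusted p = 0.017, and adjusted p = 0.22 with an estimated correlation.

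In valproic acid SOX17, an endoderm transcription factor, fell by 1.09 (SE 0.09, adjusted p = 4.6e-11), TBX1 by 0.93 (SE 0.11, adjusted p = 7.6e-08), the Nodal antagonist lft2 by 0.65 (SE 0.11, adjusted p = 3.4e-05) and SHH (ENSDARG00000068567) by 0.68 (SE 0.12, adjusted p = 3.6e-05), and 16 of 47 Nodal and mesendoderm genes fell while 1 rose. Mesodermal tbxta differed by 0.09 (SE 0.11, adjusted p = 0.61). Of 31 BMP and ventral genes, 16 fell and none rose, with GATA2 at -0.60 (SE 0.08, adjusted p = 1e-06), BMP2 at -0.66 (SE 0.10, adjusted p = 5e-06) and szl at -1.08 (SE 0.16, adjusted p = 6.6e-06). Of 32 Wnt genes, 16 fell and 1 rose, with FZD8 (ENSDARG00000045444) at -0.41 (SE 0.06, adjusted p = 2e-06) and TCF7 at -0.83 (SE 0.17, adjusted p = 0.00028). Of 31 FGF and MAPK genes, 13 fell and 2 rose, with fgfr4 at -0.35 (SE 0.06, adjusted p = 2.5e-05) and DUSP6 at -0.29 (SE 0.06, adjusted p = 0.00019). Camera called these 4 lists lower, with adjusted p = 0.00024 for Nodal, 0.00016 for BMP, 7.1e-05 for Wnt and 0.043 for FGF. Adjusted over the list alone, 17, 16, 17 and 14 members fell and 1, 0, 1 and 2 rose. With an estimated correlation they gave adjusted p = 0.22 for Nodal, adjusted p = 0.16 for BMP, adjusted p = 0.16 for Wnt and adjusted p = 0.22 for FGF. The FGF call also ended without control replicate 3 (adjusted p = 0.066), 5 (0.07) or 6 (0.072) or valproic acid replicate 3 (0.066) or 7 (0.064), and with the mean of the 2 libraries of each group and set (0.055).

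Of 31 yolk syncytial layer markers, 13 were lower and none higher in valproic acid, including hnf4b at -0.98 (SE 0.16, adjusted p = 2.3e-05), and 13 of 30 organizer, notochord and prechordal plate markers were lower with none higher. Both lists were lower by camera (adjusted p = 0.00016 and 0.00021), with adjusted p = 0.22 and adjusted p = 0.16 with an estimated correlation. In the libraries numbered 25 to 36 the yolk syncytial layer list differed from the other libraries by a median of -0.58 within valproic acid and -0.31 within controls. Within folic acid the median was -0.1 and within retinoic acid -0.01. Valproic acid against control gave a median of -0.39 for this list. Of 38 markers of the enveloping layer, the outer epithelium, 11 were lower and 2 higher, with anxa1c at -0.93 (SE 0.13, adjusted p = 8.4e-07) and evpla at -0.64 (SE 0.09, adjusted p = 1.5e-06), and camera gave adjusted p = 0.05, which did not pass. It passed in 12 of the 32 fits without 1 library (down to 0.019) and with the mean of the 2 libraries of each group and set (0.044), and gave adjusted p = 0.51 with an estimated correlation. Germ cell markers split, with 2 higher and 2 lower of 19, and 1 of 38 maternal transcripts was called. Of 35 early zygotic and pluripotency genes, 8 were lower and 1 higher, and this list was not called (camera adjusted p = 0.29). Adjusted over the list alone, the counts lower and higher were 14 and 0 for the yolk syncytial layer, 13 and 0 for the organizer, 11 and 3 for the enveloping layer, 1 and 2 for germ cells, 0 and 0 for maternal transcripts and 7 and 1 for early zygotic genes.

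Lists of chromatin, metabolic and stress genes were not called as sets in valproic acid with all libraries. Their members went both ways, but unevenly in the p53 response (9 rose and 1 fell) and the heat shock list (12 rose and 4 fell). Over all 15710 genes tested, 2505 rose and 2414 fell. The heat shock list (camera adjusted p = 0.11) was called without control replicate 1 (adjusted p = 0.04), and the histone deacetylase and acetyltransferase list (0.11) without retinoic acid replicate 3 (0.046). Neither was called with an estimated correlation in any fit without 1 library, and with all libraries they then gave adjusted p = 0.51 and adjusted p = 0.33. Adjusted over the list alone, the counts higher and lower were 8 and 14 for histone deacetylase and acetyltransferase genes, 5 and 2 for genes induced by their inhibitors, 10 and 8 for fatty acid oxidation, 12 and 6 for the heat shock list and 9 and 1 for the p53 response. Of 38 histone deacetylase and acetyltransferase genes, 8 rose and 12 fell. HDAC1 differed by 0.03 (SE 0.05, adjusted p = 0.62), the acetyltransferase gene CREBBP fell under both of its identifiers, by 0.58 and 0.61, SIRT1 fell by 0.53 (SE 0.08, adjusted p = 2.1e-06) and the corepressor gene SIN3A (ENSDARG00000079716) rose by 0.61 (SE 0.09, adjusted p = 3.1e-06). Of 27 genes often induced by inhibitors of histone deacetylases, 5 rose and 2 fell. The member with the smallest adjusted p, GADD45G (ENSDARG00000016725), fell by 2.31 (adjusted p = 6.3e-08), while synapsin syn1 rose by 1.59 (SE 0.27, adjusted p = 2.4e-05) and DPYSL2 by 1.35 (SE 0.23, adjusted p = 3.4e-05). Of 44 genes of fatty acid oxidation, 10 rose and 8 fell. CPT1A, which carries fatty acids toward mitochondria, rose by 0.88 (SE 0.07, adjusted p = 1.4e-11), PDK2 rose by 2.68 (SE 0.42, adjusted p = 8.7e-06), and HADHA, a subunit of the beta-oxidation complex, fell by 0.50 (SE 0.08, adjusted p = 6.4e-06). Of 46 heat shock, unfolded protein and integrated stress genes, 12 rose and 4 fell, with PDIA4 at 1.03 (SE 0.11), HSPE1 at 0.93 (SE 0.10) and the collagen chaperone SERPINH1 (ENSDARG00000019949) at 1.05 (SE 0.12, adjusted p = 6.3e-08). Of 30 genes of the p53 response, 9 rose and 1 fell, with SESN1 at 1.65 (SE 0.16, adjusted p = 1.6e-09) and CCNG1 at 0.40 (SE 0.08, adjusted p = 0.00014).

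In folate and one-carbon metabolism, 10 of 41 genes rose and 7 fell with valproic acid, and 11 rose and 7 fell when adjusted over the list alone. The folate carrier SLC25A32 (ENSDARG00000089791) rose by 0.64 (SE 0.09, adjusted p = 1.8e-06) and the serine synthesis gene PSAT1 by 0.68 (SE 0.12, adjusted p = 4e-05). Oxidative stress genes had 5 rises and 2 falls of 30, with glutathione reductase GSR at 0.69 (SE 0.11, adjusted p = 6e-06). Xenobiotic metabolism had 5 rises and 8 falls of 22, with cyp2y3 at -0.80 (SE 0.12, adjusted p = 3.3e-06) and tiparp at -0.50 (SE 0.07, adjusted p = 1.4e-06). Cell cycle genes had 3 rises and 11 falls of 58, and 2 rises and 10 falls when adjusted over the list alone, with the replication helicase gene MCM7 at -0.41 (SE 0.07, adjusted p = 3.2e-05) and E2F1 at -1.06 (SE 0.23, adjusted p = 0.00059). In the 4 sets of title numbers taken alone, limma called 3315, 401, 1524 and 1084 genes, and 4344 of the 4919 genes had the same sign in all 4 sets. A test of whether the effect of valproic acid differed between sets called 126 genes.

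The comparison with folic acid shows what the same handling and vehicle gave with the compound that the series design names as a negative control. No gene passed the threshold against control (limma, lowest adjusted p = 0.976), and 507 genes had an unadjusted p under 0.05, where 786 would be expected by chance. The fit counts differences between the balanced title-number sets as spread, which can lower this number. A number below chance is therefore no added evidence that folic acid has no effect. CYP26A1 differed by 0.06 (95% confidence interval -0.11 to 0.22), DHRS3 (ENSDARG00000044803) by -0.06 (-0.27 to 0.14), ALDH1A2 by -0.06 (-0.22 to 0.10) and SOX3 by -0.01 (-0.13 to 0.12). HDAC1 differed by -0.01 (-0.11 to 0.09), tbxta by 0.01 (-0.22 to 0.24) and OTX2 by 0.14 (-0.19 to 0.48). The Hox genes were less precise, with hoxb1b at 0.06 (-0.71 to 0.82) and hoxb1a at -0.59 (-1.67 to 0.49). Of 41 folate and one-carbon genes none passed, also when adjusted over the list alone, and no list was called by camera with all libraries. In each set of title numbers taken alone limma called 0 genes. Without control replicate 1 the heat shock list was called higher (adjusted p = 0.045), and without folic acid replicate 5 or 6 the Hox and Cdx list (adjusted p = 0.027 and 0.035). Neither was called with an estimated correlation in any fit without 1 library, and both then gave adjusted p = 0.99 with all libraries. Simulated changes of 2-fold in 200 of the 15710 genes were called in 67.2% of cases for this comparison, of 4-fold in 91.8% and of 1.41-fold in 30.4%.

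The compounds were also set against each other, which tests the difference between teratogens directly. Retinoic acid and valproic acid libraries differed in 4718 genes, 2284 higher and 2434 lower in retinoic acid. CYP26A1 was higher in retinoic acid by 1.83 (SE 0.08, adjusted p = 9.1e-18), DUSP6 by 0.94 (SE 0.06, adjusted p = 1.9e-14) and noxo1a by 2.07 (SE 0.12, adjusted p = 1.7e-14), while CPT1A was lower by -1.05 (SE 0.07, adjusted p = 7.9e-14). Of 25 Hox and Cdx genes, 24 were higher in retinoic acid than in valproic acid and none lower. For otx2a the difference between the 2 compounds was -0.01 (95% confidence interval -0.15 to 0.12), for OTX1 -0.03 (-0.21 to 0.15) and for FZD8 (ENSDARG00000045444) 0.04 (-0.08 to 0.16), genes that fell against control in both. Retinoic acid and folic acid differed in 136 genes, 104 higher and 32 lower. The count was 221 with the title-number sets as a block, 159 higher and 62 lower, and 54 with the mean of the 2 libraries of each group and set, 44 higher and 10 lower. Of the 115 genes called against control, 96 were among the 136 with the same sign, CYP26A1 at 1.46 (SE 0.08, adjusted p = 1.1e-14) and TSHZ3 at 2.03 (SE 0.14, adjusted p = 1.2e-12) among them. Valproic acid and folic acid differed in 4608 genes, 2346 higher and 2262 lower, of which 3732 were called with the same sign against control, including noxo1a at -1.92 (SE 0.12), CPT1A at 0.98 (SE 0.07) and SOX17 at -1.03 (SE 0.09).

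Retinoic acid and valproic acid shared 20 calls in the same direction, 15 higher and 5 lower. Independent lists of these sizes would share 14.8 and 3.38. The 20 became 41 with the title-number sets as a block, 36 with array weights and 3 with the mean of the 2 libraries of each group and set. The shared rises included INSM1 (1.62 and 0.89) and ELAVL3, and the shared falls otx2a, OTX1 and FZD8 (ENSDARG00000045444). More calls went in opposite directions. Of the genes that rose with retinoic acid, 40 fell with valproic acid, where independent lists would share 14.3, and 3 that fell with retinoic acid rose with valproic acid, against 3.51. The 40 include CYP26A1, DHRS3 (ENSDARG00000044803), MEIS1, HOXB5, FGF8, DUSP6, oc90 and tiparp. Unchanged groups simulated against the same controls shared 0 calls in all 100 draws, but at most 5 genes were called for such a group in any draw, so this gives no reference for the counts. With the controls split into odd and even replicates, retinoic acid was set against 1 part and valproic acid against the other. Then 6 and 7 calls were shared in the same direction and 27 and 13 in opposite directions. These fits called 66 and 53 genes for retinoic acid and 3330 and 3180 for valproic acid, fewer than with all controls. Their shared counts are therefore not directly comparable with those above. Across genes, which are not independent replicates, the fold changes of both comparisons correlated at 0.134, and simulated unchanged groups gave 0.509 on average, from 0.0468 to 0.78. The covariance was 0.0258, against 0.0397 in the simulation, and with split controls it was -0.0138 and 0.0137. The simulation shuffled libraries over the title-number sets, which are balanced over the real groups. Set differences therefore enter its correlation and covariance, and it gives no reference for these values either.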

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

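The tests of other splits for folic acid, of normalization by level alone and of a lag along the axis of libraries 25 to 36 were chosen only after the result was seen. Among 254 groups of 8 libraries checked for the named genes, 14 had a library set apart from the other 7 by a large gap, where 12.7 are expected at 1 in 20, so the number of such libraries is close to chance.

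In the control group, replicate 6 was lowest for ANKH (ENSDARG00000014969) at 0.902, with the next library at 5.03, for syn1 at 4.55 (next 5.73) and for sypb at 4.72 (next 6.01). Control replicate 8 was highest for HDAC1 at 14.6 (next 14.5) and lowest for TSHZ3 at 6.8 (next 7.35). In retinoic acid, replicate 3 was lowest for AMOTL2 at 10.7 (next 11.1), arhgef37 at 7.98 (next 8.67) and TBXT at 6.79 (next 7.55), and replicate 4 was lowest for dnase1l1 at 6.27 (next 6.89). In valproic acid, replicate 3 was lowest for szl at 7.34 (next 8.34), replicate 6 for OTX1 at 11 (next 11.4), replicate 7 for ATP6V1B2 (ENSDARG00000043465) at 7.15 (next 7.43) and FZD8 (ENSDARG00000045444) at 10.9 (next 11.1), and replicate 8 for HMGXB4 at 2.97 (next 4.94). Control replicate 6 and retinoic acid replicate 3 each account for 3 of the 14. Retinoic acid replicate 3 also had the lowest array weight of all libraries, 0.2414, and folic acid replicate 8 the next lowest, 0.3825. Without these 2 libraries, 97 of the 115 retinoic acid calls and 4918 of the 4919 valproic acid calls were kept with the same sign.

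For the 4919 genes changed by valproic acid, depth as a covariate left 99.7% of the calls with the same sign, which argues against depth as the whole cause. In 20 bins of expression level, 46.5% of the called genes moved in the rarer direction of their bin. Genes of the same level thus moved both ways, which a shift by level alone would not give. The near-even share itself says little, since equal distributions push rises and falls at a level toward balance (bin medians from -0.08 to 0.13). Removal of each library's trend on level left 97.8% of the calls but moved values by a median of 0.0155 (up to 0.924), against a median change of 0.608 in the called genes, and so decides little. The low part of the distribution did differ before normalization, by -0.136 in the ratio of estimated reads at the 40th to the 25th percentile (two-sided exact permutation test, p = 0.00171), so a partial contribution of normalization stays open. Of the called genes, 46.7% moved the way they moved in libraries 25 to 36 of the retinoic acid and folic acid groups. This is close to an even share, which argues against a lag along that axis as the whole cause. Hox and Cdx genes had medians of -1.24 in valproic acid against control and -1.61 in libraries 25 to 36 of the other groups. Nodal and mesendoderm genes went opposite ways (-0.25 and 0.2), so a lag of part of the genes stays open. In the 4 sets taken alone 401 to 3315 genes were called, and 4344 of the 4919 genes had the same sign in all 4. Whether valproic acid acts on these genes directly was not tested. That stays open, as does a loss of RNA common to most genes, which equal distributions hide.

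For the counts of 5 comparisons, 1 of 100 splits of the 16 libraries into 8 and 8, the real one, gave as many genes. That is the smallest share that 100 splits can give. The splits take every library as a separate unit and leave out the title-number sets. They argue against chance only as far as the libraries of a group are independent. The real counts and the highest of the other splits were 115 and 19 for retinoic acid against control, 4919 and 2528 for valproic acid against control, 4718 and 1273 for retinoic acid against valproic acid, 136 and 0 for retinoic acid against folic acid, and 4608 and 2207 for valproic acid against folic acid. The split with 2528 genes had 7 of the 8 valproic acid libraries on 1 side. For folic acid against control the real count was 0, which all 100 splits reach whatever the data, so the splits say nothing about chance. The highest other split gave 12 genes with all 4 libraries numbered 25 to 36 on 1 side.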

How the results depend on the processing

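Settings tried only after the data were seen were array weights, a mean above 5, the fits without the 2 libraries of lowest weight, without libraries 25 to 36 or without each library, the depth covariate and the removal of level trends. No value changed direction past the threshold in any setting tried. With the title-number sets as a replicate block, retinoic acid changed 199 genes, 84 at least 2-fold, retinoic and folic acid differed in 221, and 41 calls were shared by retinoic acid and valproic acid. The numbers fell short of the rule used for a pairing, since 20 of 24 pairs of groups within sets correlated above 0.1 and the lowest was -0.12. The pairs that fell short all included the control group. Libraries of a set still deviated together, with a mean correlation of deviations of 0.2 within sets and -0.099 between sets. Of 32 libraries, 27 were closest to a library of another group in their own set. This is a hint from the data and not from the design. The main fit leaves the sets out, so differences between sets count as spread in it. With the mean of 2 libraries per group and set, which leaves 4 values per group, the 4 counts given for the block were 36, 22, 54 and 3. Array weights gave 36 shared calls, and the cause was not tested. With a mean above 5, where fewer genes were tested, 31 and 643 genes changed at least 2-fold in retinoic acid and valproic acid. With an estimated correlation, camera called 1 list in retinoic acid and 0 in valproic acid. Without libraries 25 to 36, it called 1 list in folic acid, the Hox and Cdx genes (higher, adjusted p = 0.036), and the cause was not tested. Leaving out 1 library gave 85 to 124 genes for retinoic acid, 39 to 56 of them at least 2-fold, 4457 to 5325 for valproic acid, 1114 to 1224 at least 2-fold, 0 to 0 for folic acid, 4331 to 4956 between retinoic and valproic acid, 109 to 152 between retinoic and folic acid, 4217 to 4976 between valproic and folic acid and 15 to 24 shared calls. Of 184 results for named genes, 34 were no longer past the threshold with means of 2 libraries and 19 without libraries 25 to 36. The median centring, depth and level trend settings each ended 1. The setting without a filter removed nothing and tests nothing. Depth of 12 to 52 reads at the lower-quartile gene limits what can be seen among genes of low expression.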

Other observations

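The test of an earlier developmental age was chosen only after the result was seen, and the genes of the next paragraph were chosen after their values were seen. They have the smallest adjusted p by limma among called genes outside the lists.

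In valproic acid, the zinc finger gene znf526 fell by 1.73 (SE 0.10, adjusted p = 4.3e-15), and the potassium channel gene KCNK5 rose by 1.93 (SE 0.12, adjusted p = 6.2e-14). EPC1 and EPC2, which encode subunits of the NuA4 acetyltransferase complex, fell by 1.13 (adjusted p = 1.2e-12) and 1.37 (adjusted p = 2.8e-12), ZZZ3, of the ATAC complex, fell by 0.78 and kansl1a, of the NSL complex, by 0.76. The kinase gene ATM rose by 1.39 (adjusted p = 2.2e-10), the phosphatase gene PPM1L by 1.67, and SYPL2 by 1.32. SPRED3, of the family of Ras pathway inhibitors, was at 8.09 in valproic acid and 1.55 in controls. In retinoic acid, the Wnt receptor gene FZD4 rose by 1.03 (SE 0.10, adjusted p = 4.6e-08), the Wnt modulator gene DACT1 by 0.70, the organic cation transporter gene slc22a3 by 3.37, LDB2 by 1.06, NDNF by 1.17 and COL14A1 by 1.12.

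A candidate explanation for the falls of EPC1, EPC2, ZZZ3 and kansl1a in valproic acid is a fall across acetyltransferase complexes. A list of 54 other measured subunits had 15 lower and 5 higher, with a median of -0.14, and limma's camera with an estimated correlation gave a p-value of 0.13 (adjusted p = 0.26 over the 2 lists of this kind), so the data leave this open. The rises of sypb and syn1 may reflect a release of neuronal secretory genes. A list of 38 other such genes had 6 higher and 5 lower, with a median of 0.15, and the same test gave a p-value of 0.5 (adjusted p = 0.5), which leaves this open too. With syn1, which was taken out of the list after its values were seen because the test leaves out the genes that prompted it, the p-value was 0.32.

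Libraries numbered 25 to 36 stood apart in the control, retinoic acid and folic acid groups. They were not the only such set, since libraries numbered 37 to 48 stood apart in all 4 groups along the fourth principal component. Limma called 2105 genes between the 6 libraries numbered 25 to 36 and the other 18 of these groups. Of these, 1020 were higher and 1085 lower, and 539 differed at least 2-fold, with zbtb16b at -3.81, THBS1 at -3.18 and HOXB7 at -2.21. The set was picked because it stood apart in these same values, and its libraries may not be independent. The 18 include control replicate 1, which lay with this set on the second component. The counts are therefore descriptive. Hox and Cdx genes had a median of -1.61 with 22 of 25 lower, germ cell markers 0.61 and maternal transcripts 0.16. Depth is argued against by a correlation across genes, which are not independent replicates, of -0.099 with the depth slope of the other sets. An earlier developmental age may be involved, and it cannot be told apart from other causes because the larger adjusted p of the maternal and Hox lists was 0.47 with an estimated correlation (0.091 for Hox); no biological explanation named by the design was tested.

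Control replicate 1, numbered 1, deviated from the control mean in the direction of libraries 25 to 36, with a correlation across genes of 0.4 with that set and -0.18 with its own. The 2 control libraries within that set had 0.53 and 0.34.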
